A study of Aplysia californica with 8 samples.

How the data were processed

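RNA was measured on 4 arrays with 2 colours, each holding an RNA sample from kinesin immunoprecipitation (IP) and a sample of CNS total RNA from adult Aplysia californica. Per the labels' protocols, an extract of 1 CNS was cleared, mixed with 20 µg of an antibody to kinesin, and the complexes were collected on protein A/G beads, washed and their RNA isolated with TRIZOL. Total RNA of the CNS was isolated the same way. Both kinds were amplified in 2 rounds of linear in vitro transcription and labelled with Alexa Fluor 546 or 647. The amplification can distort relative levels and favours 3' ends, and the amount of RNA entering it is not given in the sources used here. The labels put every IP sample in the Alexa Fluor 546 channel and every CNS sample in the Alexa Fluor 647 channel. The series design speaks of reciprocal hybridisation, and arrays of the opposite orientation were not analysed here. Whether swapped hybridisations were averaged into the deposited columns is not given in the sources used here; if they were not, a preference of a probe for a dye stays in every difference.

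The deposited table held 1 column of log2 values per sample, that is per dye channel. The submitters' processing notes name Agilent Feature Extraction. Its version, the background correction, the dye normalization, any scaling between columns and the reason for empty cells are not given in the sources used here. That the values are log2 and not another logarithm was taken from their range, and the base is not given in the sources used here. The direction is that of the sample in each column. Medians of the columns over the tested probes were 0.11 to 0.13 higher in the IP channel on each array, while the median of the probes' own differences was between -0.02 and -0.004. Probe differences thus centred near 0 on every array; whether the authors scaled the channels to give this is not given in the sources used here, and a shift common to all transcripts would not be seen if they did. The difference of column medians was under the limit of 0.5 set before the data were examined, so the values were used as deposited. Of the cells, 0.754% were empty, 272 to 420 per sample. The 1012 probes with an empty cell, 28 of them without any value, were left out of the tests. No background signal, flag or detection call was used here, so no probe could be called absent, and a fold against a value in the dim range depends on how low values were made.

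Probe IDs were plain numbers. None of them matched an ID of the AplCal3.0 gene table, and no table pairing probes with genes was used here. The gene-level fit and the tests of 26 gene lists (motors, cytoskeleton, translation, mitochondria, synapse, neuropeptides, markers of muscle, sheath, haemocytes and glia, and others), planned before the data were examined, could therefore not be run. The planned rule for this case names the 2 probes with the largest positive and the 2 with the largest negative difference among those past the threshold, of the same sign on all 4 arrays and with a mean over the 8 samples at or above that of the median probe.

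The comparison was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, group and array as terms, over 42681 probes, with 3 residual degrees of freedom per probe and Benjamini-Hochberg adjustment. The array was a block because the labels name it for each sample. Deviations from the group means correlated across probes between samples of one array at 0.147, 0.065, 0.107 and 0.110 for arrays 1 to 4, each the highest for that sample, and between -0.216 and 0.053 for other pairs. Deviations sum to 0 within a group, so positive values for one array push those of other pairs down. Among probes with a mean of 7 or more the own-array values were -0.047, -0.133, -0.044 and -0.037, and 0 of 4 were the highest. Summaries of whole samples were compared by exact permutation tests, paired over the 16 sign flips of 4 arrays and unpaired over 70 relabellings. The comparison of the brightest probes, the classes of mean signal, the bounds of 6, 7, 8, 9 and 12 and the summaries of whole samples were chosen after seeing the data.

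The fit was tested on simulated data with the real probes' means and residual spread over the same 42681 probes. With 200 probes changed, it recovered 0 of 50 at a log2 size of 0.5, 29 of 50 at 1, 36 of 50 at 2 and 41 of 50 at 3, and 9 of 115 calls were false. With 8536 probes changed, it recovered 56.6%, 77.7%, 91.2% and 96.3% at these sizes, and 4.78% of the calls were false. The simulated noise was independent between probes and equal in spread in both groups, which the data are not. The false shares are therefore not error rates of the real calls. The alternatives were no block, other scalings, a filter on dim probes, another variance prior, a size threshold, each array left out, and, chosen after seeing the data, stricter filters, a floor on low values with and without a filter, a random block and the inclusion of probes with empty cells. Each changed 1 choice, except the variance prior, which was made both trended and robust, and the floor. The floor changed the values and the probes tested together: without the filter it still left out probes with no value over 6, which it makes constant.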

Results

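RNA recovered with the motor protein kinesin was compared with total RNA of the central nervous system (CNS) of the sea hare Aplysia californica, a marine mollusc whose large neurons are used to study synaptic plasticity. Kinesin moves cargo along microtubules towards the axon terminal, and the comparison asked which transcripts travel in, or are held by, kinesin complexes. There were 4 samples of RNA from immunoprecipitation (IP) with 20 µg of an anti-kinesin antibody and 4 samples of CNS total RNA. Both came from adult animals of 50 to 90 grams. Each of 4 arrays with 2 colours carried an IP sample labelled with Alexa Fluor 546 and the CNS sample of the same number labelled with Alexa Fluor 647. The series design calls the samples biological replicates, and the labels do not say whether an IP sample and the CNS sample of its number came from the same animal.

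The deposited values were log2 signals, and no depth applies to them: the number of arrays limits the precision. Of 43693 probes, 42681 had a value in all 8 samples and were tested. The median log2 signal of these probes lay between 5.36 and 5.38 in the IP samples and between 5.24 and 5.27 in the CNS samples. Within the IP group, Spearman correlations across probes ran from 0.922 to 0.946, and within the CNS group from 0.896 to 0.964. Between the IP and CNS samples of one array they ran from 0.840 to 0.878, with probes not being independent replicates. No samples held identical values. The first principal component, with 51.3% of the variance, had all 4 IP samples on one side and all 4 CNS samples on the other. The second, with 14.0%, had CNS samples 1 and 2 at -74.0 and -51.5 and CNS samples 3 and 4 at 27.0 and 77.5, while the IP samples lay between -11.6 and 21.8. The probes were known only by number, so transcripts are described here by their signal and not by gene.

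Kinesin IP RNA and CNS total RNA differed at many probes, most of them at low signal. By limma with the array as a block and Benjamini-Hochberg adjustment, 9712 probes (22.8%) passed an adjusted p of 0.05. Of these, 4538 were higher and 5174 lower in the IP RNA. Most calls were dim: 3899 of the higher and 3972 of the lower had a mean under 7. At a mean of 7 or more, 639 were higher and 1202 lower. Many calls were small, with 1126 higher and 1840 lower calls under 1.41-fold. Of all tested probes, 51.7% had the same sign on all 4 arrays, against 12.5% if signs were even and independent between arrays. A shift of one channel shared by all 4 arrays would also raise this share. It therefore does not separate RNA from dye. Of the differing probes, 3811 were at least 2-fold apart, 2416 higher and 1395 lower in the IP. At least 4-fold apart were 934 higher and 361 lower probes, and at least 8-fold apart were 279 higher and 91 lower probes. Leaving out array 1, 2, 3 or 4 gave 637, 683, 605 or 756 higher and 151, 159, 169 or 246 lower probes at 4-fold, and 206, 217, 198 or 221 higher and 39, 42, 44 or 71 lower probes at 8-fold. The excess of higher probes at 4-fold depended on low values. Among the 13481 probes at 6 or more in at least 4 samples, it was 715 higher and 454 lower as deposited, and turned to 161 and 362 with values under 6 raised to 6. Among probes with a mean of 7 or more, 156 were higher and 397 lower. With the arrays as the only replicates, leaving out array 1, 2, 3 or 4 lowered the count of all differing probes to 2479, 2560, 3485 or 5202. Without array 1 or 2 more probes were higher than lower (1489 and 990 without array 1, 1543 and 1017 without array 2). The share of calls that were higher in the IP was 46.7% with the values as deposited. It was 29.8% after centring each column on its median, 39.8% after quantile normalization and 57.2% after loess within arrays. The median of all differences moved by -0.11 under the centring.

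**Figure D1:**
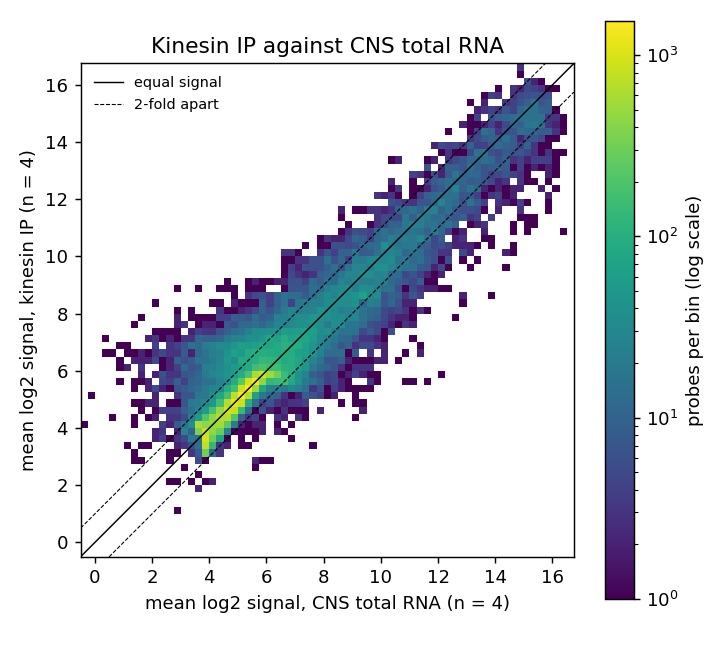
Mean log2 signal of the 42681 tested probes in kinesin IP RNA (vertical axis, n = 4) against CNS total RNA (horizontal axis, n = 4), in bins coloured by their number of probes on a log scale, with a solid line at equal signal and broken lines at a 2-fold difference. Most probes lie in a narrow ridge at low signal, and probes off the ridge are spread to both sides, with 2416 called at least 2-fold higher and 1395 at least 2-fold lower in the IP.

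By the labels, every difference in this comparison is one between Alexa Fluor 546 and Alexa Fluor 647 as well as one between IP and CNS RNA, since all 4 arrays have the same dye orientation. The series design speaks of reciprocal hybridisation, and whether swapped hybridisations were averaged into the deposited columns is not given in the sources used here. IP from a control antibody was not analysed here, so the values compare RNA of the kinesin IP with all RNA of the tissue and not with RNA that sticks to beads or antibody.

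The probes at least 2-fold higher in the IP lay at lower signal than those at least 2-fold lower. Among the 2416 probes at least 2-fold higher, the median of the group means was 6.86 in IP RNA and 5.02 in CNS RNA. In 1422 of them (58.9%) the CNS mean lay below 5.26, the CNS signal of the median probe. By definition, as many tested probes lie below that signal as above it. Choosing probes by a positive difference also favours low CNS values. Among the 1395 probes at least 2-fold lower, the median of the group means was 9.11 in CNS RNA and 7.15 in IP RNA, and in 108 (7.74%) the IP mean lay below the median probe of the IP, 5.43. The excess of higher probes among large differences turned when values under 6 were raised to 6. Among the 13481 probes at 6 or more in at least 4 samples, 1932 were at least 2-fold higher and 1661 at least 2-fold lower with the values as deposited, and 1134 and 1357 with the low values raised. With low values raised among all 19245 probes that had a value over 6, the counts were 955 and 1048. At least 8-fold apart among the 13481 probes were 203 higher and 110 lower as deposited, and 9 and 81 with low values raised.

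Probes clear in one RNA and at low signal in the other were counted without a test and with the values as deposited only. Column medians were higher in the IP on each array, so fixed bounds can favour the IP. Several probes may measure one transcript. At a log2 signal of 7 or more in all 4 IP samples and under 6 in all 4 CNS samples there were 161 probes, against 28 probes in the opposite arrangement. With a lower bound of 8 in place of 7 there were 8 probes and 0 probes. By group means among the called probes, 498 had an IP mean of 7 or more and a CNS mean under 6, and 212 had the opposite. At a bound of 9 the order turned, with 5 probes bright in the IP and 14 bright in the CNS.

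The balance of higher and lower probes differed along the range of signal. Among the 13748 probes with a mean over all samples from 5 to 6, 1371 were higher and 198 lower in the IP. Among the 5150 probes under 4, 702 were higher and 1683 lower, and 92 and 5 of these were at least 2-fold apart; under loess the order turned, with 1158 higher and 963 lower. Among the 4288 probes at 9 or more, 215 were higher and 706 lower, with a median difference of -0.32. This direction of the bright probes was kept under centring on the column median (191 higher, 931 lower), was nearly lost under loess within arrays (365 higher, 430 lower) and turned under quantile normalization (525 higher, 412 lower). For probes from 5 to 6 the excess of higher calls was kept under loess (1318 higher, 203 lower) and under quantile normalization (1096 and 745) and was small after centring on the median (1121 and 1010). Leaving out array 1, 2, 3 or 4 lowered the counts and kept their order. From 5 to 6 they were 600 higher and 16 lower, 642 and 13, 641 and 27, or 936 and 61. Under 4 they were 77 and 208, 50 and 210, 92 and 793, or 122 and 739. At 9 or more they were 85 and 205, 110 and 227, 75 and 287, or 114 and 475.

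**Figure D2:**
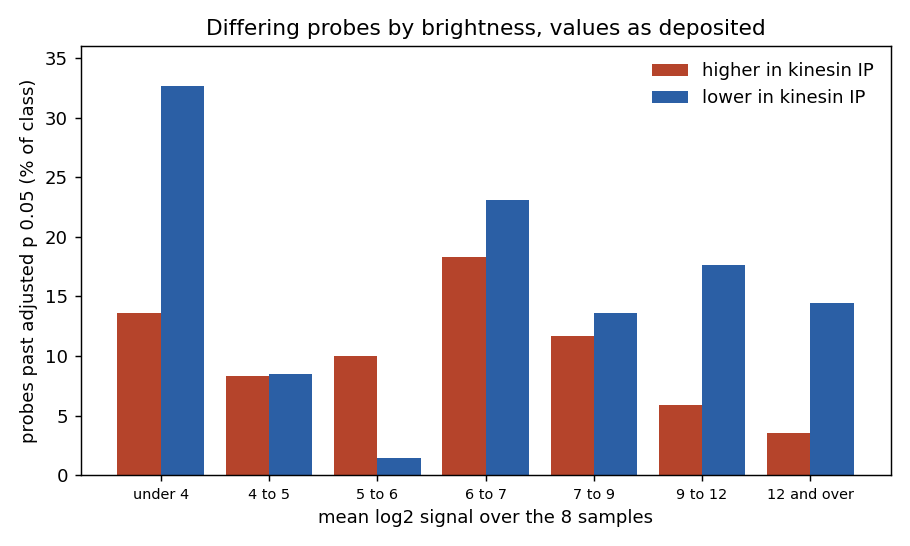
Share of probes past an adjusted p of 0.05 (vertical axis, percent of the class) in 7 classes of mean log2 signal over the 8 samples (horizontal axis), higher (red) or lower (blue) in kinesin IP than in CNS total RNA, with the values as deposited. With these values, higher calls outnumber lower ones only in the class from 5 to 6 (9.97% against 1.44%), and at 12 and over 3.53% were higher and 14.5% lower; higher calls also outnumbered lower ones under 4 with loess within arrays (1158 and 963) and at 9 or more with quantile normalization (525 and 412).

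The probes brightest in CNS RNA were examined with the ranking and the difference taken from separate arrays, so that a probe was not chosen by the value it was measured with. Ranking in CNS samples still favours probes that have more signal in CNS than in IP RNA on every array. A negative median for such a list can therefore come in part from the ranking. Brightness also depends on the probe's own affinity, so the ranking is one of probes and not of transcript abundance. The 427 probes brightest in CNS samples 1 and 2 (1% of those tested) had a median IP minus CNS difference of -0.63 on array 3 and -0.28 on array 4, and 71.9% were lower in the IP by the mean of these arrays. The 427 brightest in CNS samples 3 and 4 had medians of -0.73 on array 1 and -0.59 on array 2, and 80.3% were lower in the IP. Ranked in the IP samples instead, the medians were -0.12 and 0.29 on arrays 3 and 4, and -0.14 and -0.20 on arrays 1 and 2. With the columns scaled in other ways, the medians for the CNS lists were smaller in size under loess (-0.26 and -0.25) and quantile normalization (-0.21 and -0.32) than as deposited (-0.46 and -0.68). They were -0.57 and -0.80 after centring on the column median. Under quantile normalization all columns share 1 distribution, so a negative sign is to be expected from ranking in CNS RNA. Lists ranked in the IP were not measured under these scalings, so the sign adds no support. The lists overlapped between the kinds of RNA: 65.1% and 59.5% of the CNS lists were among the 427 brightest IP probes of the other arrays. By comparison, 82.7% were again among the brightest in the other CNS samples.

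Some summaries of how the signal was spread over probes differed between IP and CNS samples in the same direction on 4 of 4 arrays. By the labels, these samples also differ in dye. On average, 8883 ± 163 probes reached 7 in IP RNA and 8365 ± 262 in CNS RNA (SD, n = 4 each), more in the IP on 4 of 4 arrays. At 12 or more there were 1486 ± 52.4 probes in the IP and 1730 ± 35.7 in the CNS, fewer in the IP on 4 of 4 arrays. The brightest 10% of probes held 92.9% ± 0.507 of the summed signal in the IP and 94.4% ± 0.451 in the CNS. At 8 or more the numbers were 6040 ± 65.8 and 6052 ± 71.2 and did not differ beyond the spread between samples (two-sided exact permutation p = 1 paired by array, 0.886 unpaired). For the other 3 measures the two-sided exact permutation test gave p = 0.125 paired by array, the smallest that 4 pairs allow, and p = 0.0286 unpaired, the smallest for 4 against 4 samples. Adjusted over the 12 summaries tested, these became 0.167 and 0.049. The differences depended on the scaling. That at 7 or more was 518 probes, and 90 after centring on the column median. That at 12 or more was -243.75, and -99.75 under loess, and that in the percent of signal held by the brightest 10% was -0.49 under loess. All 3 are 0 under quantile normalization, which makes all distributions equal.

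**Figure D3:**
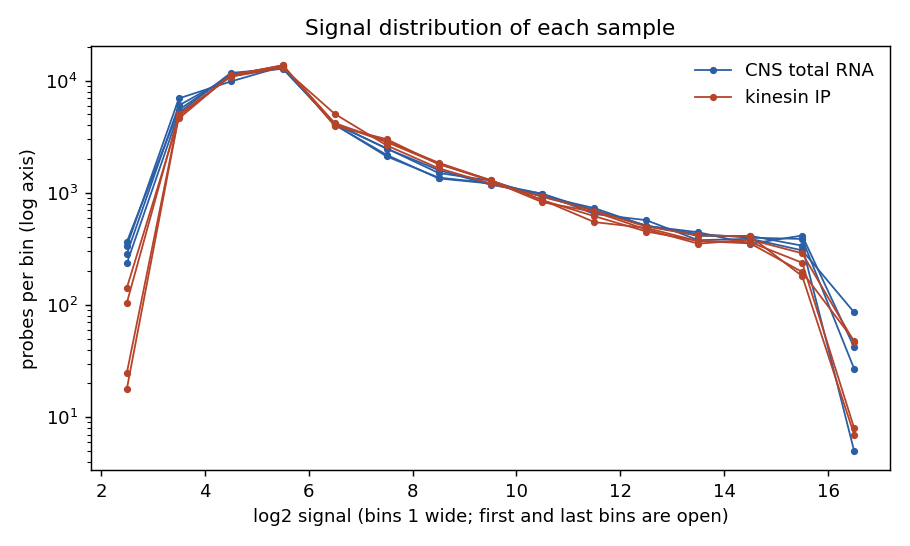
Number of probes per bin of log2 signal (vertical axis, log scale) against log2 signal (horizontal axis) for each of the 4 kinesin IP samples (red) and 4 CNS total RNA samples (blue). From 7 to 8 the IP samples (2648 to 3007 probes) lie above the CNS samples (2112 to 2486), while at the bright end they lie below them in the bins from 12 and from 15, overlap in those from 13, 14 and 16, and sum to 1423 to 1541 probes at 12 or more against 1680 to 1761 in the CNS samples.

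The differences were repeated between arrays. Across probes, the IP minus CNS differences of separate arrays correlated with Pearson's r from 0.529 to 0.678 over all probes, and from 0.457 to 0.593 over the 7923 probes with a mean of 7 or more. The highest values were those of arrays 1 and 2 and of arrays 3 and 4. Of 3771 probes at least 2-fold higher in the IP by the mean of arrays 1 and 2, 88.1% had the same sign and 64.9% were again at least 2-fold higher by the mean of arrays 3 and 4. Of 2647 probes at least 2-fold lower on arrays 1 and 2, 87.8% had the same sign and 55.7% were again at least 2-fold lower. Chosen on arrays 3 and 4 and measured on arrays 1 and 2, 90.6% of 4181 higher probes had the same sign and 58.6% were again at least 2-fold higher, and 84.1% of 3057 lower probes had the same sign and 48.2% were again at least 2-fold lower.

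A rule fixed beforehand chose the probes to be named: the largest differences among calls of the same sign on all arrays, with a mean signal at or above that of the median probe. Probe 29582 was 6.02 ± 1.03 (SE) higher in the IP on the log2 scale, with an adjusted p of 0.0251 by limma. Its signal was 8.95 ± 0.261 in IP RNA and 2.92 ± 2.55 in CNS RNA (SD, n = 4), with 1 CNS value at -0.83. Probe 2512 was 5.27 ± 0.51 higher, with an adjusted p of 0.00873 by limma, at 8.83 ± 0.341 in IP RNA and at 3.56 in CNS RNA, where single values ran from 1.86 to 4.67. Probe 27545 was lower by 6.28 (log2 difference -6.28 ± 1.24), at 5.77 ± 1.87 in IP RNA and 12.05 ± 1.97 in CNS RNA, with an adjusted p of 0.0336. Probe 1781 had a difference of -6.08 ± 1.15, at 5.67 ± 1.76 and 11.75 ± 2.01, with an adjusted p of 0.0304. Probes 27545 and 1781 ran nearly in step over the arrays, with differences of -3.26 and -3.22 on array 1. Probes 29582 and 2512 did so in the IP samples, at 9.20 and 9.14 in sample 1 and 8.63 and 8.42 in sample 2. Whether either pair measures the same transcript is not known, so the 4 probes may not be separate examples. The CNS means of both higher probes lay below the CNS median probe. With values under 6 raised to 6, the differences of probes 29582 and 2512 shrank to 2.95 and 2.83, and those of probes 27545 and 1781 were -5.38 and -5.17. Probe 2512 passed the threshold in all 4 fits that left out an array. Probe 29582 missed it without array 1 (6.58), array 2 (6.53) or array 4 (6.18), and passed it without array 3, where its difference was smaller (4.81). Probes 27545 and 1781 missed it without array 1 (-7.28 and -7.03), array 2 (-6.61 and -6.34) or array 3 (-6.31 and -6.12), and passed it without array 4, where their differences were smaller in size (-4.91 and -4.82). Array 3 had the largest difference of probe 29582 (9.68), and array 4 those of probes 27545 and 1781 (-10.4 and -9.85).

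**Figure D4:**
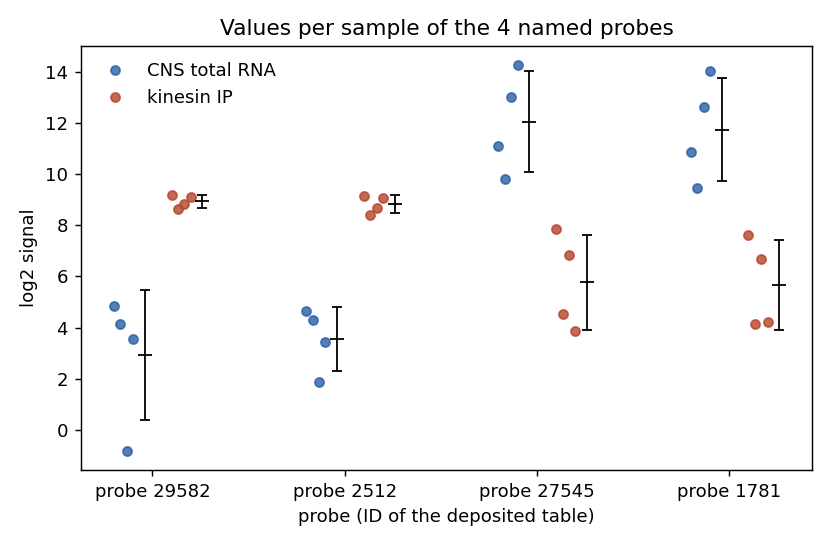
Log2 signal (vertical axis) of the 4 named probes in each kinesin IP (red) and CNS total RNA sample (blue), with the mean and SD (n = 4) as bars beside the points. For each probe the samples of both kinds do not overlap, and the CNS values of probe 29582 include 1 at -0.83.

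The spread between replicates differed by the level of signal. Among the 34758 probes with a mean under 7, the median SD was 0.039 between IP samples and 0.163 between CNS samples. Among the 7923 probes at 7 or more it was 0.468 and 0.471.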

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

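The tests of spread, of array numbers and of competition in this part, and the look at probes with empty cells, were chosen after the result was seen, and those of splits, dye and intensity trend before. Among the probes left out of the tests for an empty cell, 611 had at least 2 complete arrays. Of these, 251 were higher in the IP by at least 1 (log2) on every complete array, against 121 that were lower by as much. These probes were picked by an empty cell, and no matching share of the tested probes was taken. Among tested probes, the excess of higher probes at large differences turned when low values were raised. Whether the excess among probes with empty cells also depends on low values was not tested. A further 80 probes had values in all 4 IP samples and in no CNS sample, with a median of 6.85, and 53 had values in all 4 CNS samples and in no IP sample, with a median of 10.3. None of the 36 groups of 4 values tested held a sample far from the others by Dixon's test, where chance gives about 1 in 20.

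The number of differing probes was set against other splits of the samples. Without the block, 13743 probes differed between IP and CNS. Of the 35 splits of the 8 samples, 1 (the real one) gave as many, and the highest of the others gave 4. That share is under 0.05 and argues against chance only for this fit, which ignores the shared array. With the block, as in the report, the real split gave 9712 and the highest other of the 8 splits that part every array gave 0, and these splits are too few for a share under 0.05. The splits do not bear on the dye: by the labels 0 of the 4 arrays had the opposite dye orientation, and whether swapped hybridisations were averaged into the columns is not known, so a dye preference of single probes and a difference between IP and CNS RNA cannot be told apart for any called probe, and RNA bound without kinesin stays untested as well.

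Values of dim probes varied far less between IP samples than between CNS samples. Among probes with a mean under 7 the median CNS SD was 4.13 times the median IP SD, and among probes at 7 or more 1.01 times. For IP samples that repeat fewer animals or one extract, a lower IP SD was predicted among bright probes too, where it was the lower one in only 51.1% of probes. Spread added by the IP itself was not measured and could hide a lower spread between extracts. Repeated animals or extracts therefore stay open. The limit to dim probes is consistent with a different background of the channels near the detection limit; dye and RNA share the channel, so which of them sets it stays open. The fit tests the difference of the channels. Under 4 its median SD was 0.120, with 0.102 between CNS and 0.043 between IP samples, so the IP spread added little to it. From 7 to 9 it was 0.700. The low spread of dim probes may let small differences pass, which was not tested. Among probes under 4, 702 were higher and 1683 lower in the IP as deposited, and 377 and 2275 after centring on column medians. After loess the order turned, with 1158 higher and 963 lower.

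In bright probes, the channels of one array deviated in opposite directions. The correlation of their deviations from the group means, averaged over the 4 arrays, was 0.139 for probes under 5, 0.249 from 5 to 7, 0.062 from 7 to 9, -0.127 from 9 to 12 and -0.41 at 12 or more, and at 9 or more the real pairing was the lowest of all 24 pairings of IP with CNS samples (-0.21, next lowest -0.19). In 8 of 8 samples the dim probes deviated most alike with the same array number, which argues against wrong array numbers. The fall from 7 upwards is what competition of the channels for the same spot at high signal predicts. At 9 or more, however, own-array values ran from -0.331 to -0.130 and those of pairs from different arrays from -0.297 to 0.341. The opposition was thus not confined to channels of one array, and competition stays open. The highest of the 24 pairings (0.233) joined IP samples 1 and 2 with CNS samples 4 and 3. In it, IP samples 3 and 4 were joined with CNS samples 1 and 2. Whether the opposition follows a split of arrays 1 and 2 against 3 and 4 was not tested. Competition also does not bear on the higher value from 5 to 7 than under 5. An intensity-dependent normalization stays open, since removing each sample's trend with intensity left the correlation at -0.21 at 9 or more but took out almost nothing (SD of the trend 0.0076 to 0.0431, of the deviations 0.392 to 0.64), and a difference between animals in how much of a transcript the IP takes up is untested, since the labels do not tie IP and CNS samples to animals.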

How the results depend on the processing

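The count of 9712 differing probes (4538 higher, 5174 lower; 3811, 2416 and 1395 at least 2-fold) lay between 8976 and 14468 in total under no replicate block (13743 probes, 6485 higher and 7258 lower), loess within arrays (8976), quantile normalization (10509), a trended robust prior (11177), centring on column medians (11706) and, added after seeing the data, inclusion of probes with empty cells (9812) and a random block (14468). The block is the shared array, and the fit without it kept 9025 of the 9712 calls. Single directions moved further under centring, where 8222 probes were lower, and under the random block, where 6833 were higher. Leaving out the dimmest 25% of probes gave 4776 (2631 higher, 2145 lower) among fewer probes tested. A size of at least 2-fold gave 3811 (2416 and 1395) by construction. Added after seeing the data, probes with a mean of 7 or more gave 1614 (564 and 1050), 1609 and 564 of them at least 2-fold in total and higher, among 7923 tested. Probes at 6 or more in at least 4 samples gave 4559 (2269 and 2290) among 13481 tested, and a floor at 6 on these gave 4074 (1980 and 2094), with 2491 at least 2-fold and 1134 of these higher. The floor without this filter gave 3584 (1826 and 1758), with 2003 at least 2-fold and 955 of these higher. The excess of higher over lower probes at 2-fold (63.4% higher) was kept under that filter alone (53.8%) and turned with both floors (45.5% and 47.7%) and for a mean of 7 or more (35.1%). Leaving out 1 array gave 2479 to 5202 calls, 1489 to 2535 higher and 990 to 2667 lower, and at 2-fold 1965 to 2951, 1335 to 1871 and 629 to 1080, with fewer samples. Under loess 2 and under quantile normalization 3 of the 9712 probes turned their sign, none past the threshold again. The mean excess of IP over CNS in probes at 7 or more was 518, and 90 after centring and 0 after quantile normalization, which makes the distributions equal. That at 12 or more was -243.75, and -99.75 under loess and 0 under quantile normalization. The IP minus CNS difference in the percent of signal held by the brightest 10% was -0.49 under loess and 0 under quantile normalization. Leaving out 1 array gave 407 to 665, -270.0 to -212 and -1.71 to -1.34 for these. Apart from filters, thresholds, fewer samples and quantile normalization, the cause of these shifts was not tested. Named probes kept their sign in every scaling, filter and floor that tested them and lost the threshold only where an array was left out; 29582 and 2512 are not among probes with a mean of 7 or more. Alternatives for genes, gene lists and named genes (the highest-mean probe of a gene, camera with an estimated correlation, fry and the settings above) were not run, since no table pairing probes with genes was used here. Low signal limits the folds of dim probes, as no detection call was used.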

Other observations

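CNS samples 1 and 2 correlated at a Spearman's rho of 0.964 across probes and samples 3 and 4 at 0.952, while the other CNS pairs lay between 0.896 and 0.942. Split as samples 1 and 2 against 3 and 4, 7489 probes had an unadjusted limma p under 0.05 and 0 passed adjustment, against 797 and 971 unadjusted for the other ways of splitting these samples into pairs. The IP samples on the same arrays gave 1893, 1572 and 1472. The splits were examined after the structure had been seen, and no explanation was tested.

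The brightest 1% of probes held 48.8% ± 2.16 of the summed signal in the IP and 46.9% ± 2.59 in the CNS (SD, n = 4), a difference within the spread between samples (two-sided exact permutation p = 0.25 paired by array). The minimum of each CNS sample was below that of every IP sample: it lay, over tested probes, between -8.29 and -3.17 in the CNS samples and between -2.75 and 0.72 in the IP samples. Of probes with empty cells, 44.9% had a median signal of 7 or more, against 18.8% of tested ones. The median of a probe with empty cells leaves those cells out. If cells were emptied for low signal, this raises it, so the measures are not alike.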
